A study of Homo sapiens with 24 samples.

How the data were processed

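The arrays were Affymetrix HG-U133 Plus 2.0 expression arrays, which read the end of each transcript nearest its poly(A) tail with sets of short probes, and 1 array was run per sample. Per the labels, total RNA was extracted with a Qiagen kit and labelled with biotin by the 3′ IVT Plus kit. Per the labels, the cell lines carried a stable lentiviral shRNA under puromycin selection, and the BLID shRNA groups came from 1 shRNA clone. The labels do not say whether the replicates of a group came from separate infections, so the p-values measure the spread between these samples only. MDA-MB-231 and LCC9 were grown in DMEM with Glutamax and MCF7 in DMEM with glutamine per the labels, so cell line and medium differed together wherever MCF7 was compared with another line.

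The deposited values are log2 probe set signals, 1 column per array. Per the submitters' processing notes they came from Affymetrix Expression Console, whose version is not given. The algorithm that corrected background, normalized the arrays and summarized the probes is not given in the sources used here. The distributions of the columns were nearly the same on every array, and no further normalization was applied in the main analysis. Depth does not apply to arrays: the number of arrays, 4 per group, limits the precision.

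The column of MDA-MB-231 BLID shRNA replicate 1 holds the value 7.51 in 9950 consecutive entries, and none of the other 23 arrays holds a run of at least 10 equal values. These entries were treated as missing, a choice made after the data were examined. It left 44725 of 54675 probe sets with a value on all 24 arrays, and 842 of the tested genes lacked that array's value. Where the probe sets of a gene were averaged, the mean of that array used only its probe sets with a value.

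Of 54675 probe sets, 41097 carried a single gene symbol in the platform table, 1801 carried several and 11777 carried none. The gene IDs of 41043 single-symbol probe sets matched the reference gene table (assembly GRCh38.p14), which was used for names and neighbouring genes only, so no coordinates are given. The probe set with the highest mean over all arrays stood for each of 19775 genes. A gene was tested if the mean of at least 1 cell line reached 5.92, the median of all probe sets and arrays, which left 13580 genes. The table holds no detection calls. Where 1 of the compared groups averaged below 5.92, the difference is read as a lower bound for that probe set only. Other probe sets of the gene may show a smaller change. Where both groups averaged below 5.92, no difference of a single gene is given in the results, apart from BLID. Probe sets with several or no symbols were left out of the comparisons between genes and are described among the results set aside for a closer look. All columns were used.

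The 6 group means were fitted over the 24 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, 18 residual degrees of freedom). Contrasts were BLID shRNA minus control shRNA within each line, the differences between these effects, and each control group minus the MCF7 control group. The p-values were two-sided and adjusted by Benjamini-Hochberg over the genes tested in each comparison, and an adjusted p below 0.05 counted as a change. Single values such as the BLID signal were also compared by an exact two-sided permutation test over all assignments of the arrays of a line, whose smallest possible p is 0.0286 with 4 against 4 arrays. Correlations between the effects in a pair of lines run across genes, which are not independent replicates, so their p-values came from exchanging the arrays within the lines. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.

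There were 37 gene lists, written from general knowledge before the data were examined: BCL2 family, caspases and apoptosis execution, p53 targets, interferon response, MHC class I antigen presentation, NF-kB targets and cytokines, epithelial junction and keratin genes, mesenchymal genes and EMT (epithelial to mesenchymal transition) regulators, collagens and matrix proteins, integrins and adhesion, estrogen receptor targets, luminal lineage, MDA-MB-231 marker genes (basal B), stem cell and drug resistance genes, cell cycle G2/M, cell cycle G1/S and DNA replication, hypoxia and glycolysis, oxidative phosphorylation, unfolded protein response and ATF4 targets, heat shock and proteostasis, cholesterol synthesis and uptake, fatty acid synthesis and lipid storage, NRF2 and antioxidant genes, YAP and TEAD targets, TGF-beta targets, PI3K-AKT-mTOR pathway, MAPK feedback and immediate early genes, autophagy and lysosome, mitochondrial dynamics and mitophagy, DNA repair, ribosomal proteins, RNA interference machinery, the BLID chromosome 11q24 neighbourhood, and marker genes of fibroblasts, of blood cells, of endothelial cells and of melanoma and neural cells. Each list with at least 5 measured members was tested by limma's camera with a preset inter-gene correlation of 0.01 and adjusted over the 37 lists of a comparison. Each call was repeated with the correlation estimated from the arrays, and fry was run beside it. The mean of each list per array was compared by an exact permutation test, which was added after the data were examined. A list of let-7 target genes was added after DICER1 had been seen to be higher.

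The design, the contrasts, the filter, the lists, the alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names BLID, the 10 largest changes in each direction per line among genes that passed the adjusted threshold with the groups of 4 arrays fully apart, and up to 10 genes changed in the same direction in all 3 lines with the largest smallest change. It further names up to 4 members per called list with the smallest adjusted p, the 5 genes with the strongest difference between lines among those changed in opposite directions, and up to 3 members of the luminal, basal B and estrogen receptor lists per baseline comparison. Uncharacterized locus symbols, XIST and Y-linked genes were left out. Limiting the list members in MDA-MB-231 to 2 per list was decided after the data were examined, and genes outside the rule are named as such.

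Alternatives changed 1 choice at a time: equal medians, quantile normalization over all 24 arrays or within each line, no filter or a filter at the upper quartile, every probe set tested, the mean of all probe sets of a gene, no probe sets marked _x_at or _s_at (which may read related transcripts), only the 8 arrays compared, eBayes without trend or with a robust prior, array weights, a block for replicate number, a covariate for RNA quality, a 2-fold threshold, camera on ranks, fry, and leaving out each array. Keeping the run of equal values, leaving out the 4 arrays with the largest difference between 3′ and 5′ control probe sets, and the correlation without interferon and MHC genes were added after the data were examined. A pseudocount was not varied, because the values are already on a log2 scale.

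Simulated data kept the mean of each gene per line and its spread pooled over the 6 groups, with independent noise (13580 genes, 50 changed genes per size). In these data limma found 41 of 50 genes changed by 0.5 log2 units in MDA-MB-231, 35 of 50 in LCC9 and 36 of 50 in MCF7. At 1 log2 unit it found 48, 50 and 50 of 50. Of 13380 unchanged genes, 9, 12 and 7 were called. The shifted list was found in each line, and 0 of 36 unshifted lists were called. Because the genes were simulated independently, this cannot show how often lists of correlated genes are called in error.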

Results

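Gene expression was measured in 3 human breast cancer cell lines that carried a stable shRNA directed at BLID or a control shRNA, with 4 arrays in each of 6 groups and 24 arrays in all. MDA-MB-231 is a mesenchymal-like line without estrogen receptor, MCF7 is a luminal line with estrogen receptor, and LCC9 is an MCF7 derivative that grows without estrogen and in the presence of antiestrogens. BLID codes for a cell death inducer with a BH3-like motif, and the comparison of the groups within each line asked which genes change when it is targeted. Median log2 signals lay between 6.24 and 6.31 on the 24 arrays, over 44725 probe sets with a value on every array. Replicates spread more in the control groups: the median SD of a gene was 0.15 in MDA-MB-231 controls against 0.10 in the arrays labelled BLID shRNA, 0.12 against 0.08 in LCC9 and 0.17 against 0.08 in MCF7. The 4 arrays per group limit the precision.

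No lower BLID signal passed a test in the arrays labelled BLID shRNA of any of the 3 lines. In MDA-MB-231 its only probe set averaged 7.62 ± 0.13 (log2, SD, n = 3) in these arrays and 7.24 ± 0.60 (n = 4) in the controls, a difference of 0.38 with a 95% interval from -0.02 to 0.78. An exact two-sided permutation test gave p = 0.314 for this difference. LCC9 averaged 4.36 ± 0.12 (n = 4) against 4.27 ± 0.21 (n = 4), a difference of 0.09 from -0.28 to 0.46 (exact permutation p = 0.486). MCF7 averaged 4.18 ± 0.15 (n = 4) against 4.23 ± 0.19 (n = 4), a difference of -0.05 from -0.42 to 0.32 (exact permutation p = 0.743). In LCC9 and MCF7 the signal lay below 5.92, the median of all probe sets, so a lower level could not be measured there. BLID lies within MIR100HG, whose brightest probe set averaged 10.21 ± 0.07 and 10.17 ± 0.46 (n = 4 each) in MDA-MB-231 and at most 3.41 in the other lines. The limma adjusted p for BLID in MDA-MB-231 was 0.26, and without control replicate 3 the difference was 0.66, past limma's unadjusted threshold of 0.05 and again with the higher signal in the arrays labelled BLID shRNA. The groups are therefore named by their labels, and no direction given here is tied to a measured loss of BLID.

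**Figure D1:**
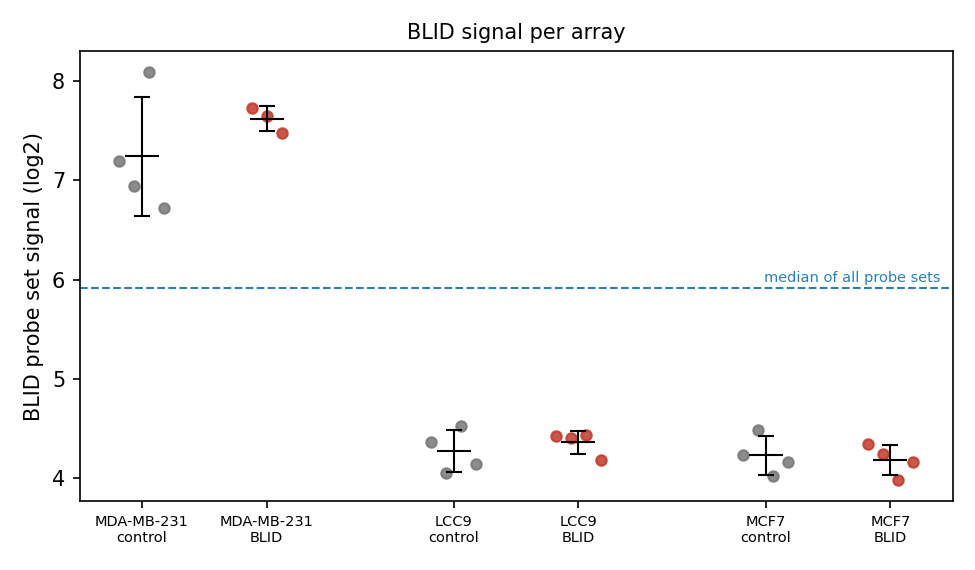
BLID signal (log2, vertical axis) on each array by cell line and shRNA label, with points for arrays, bars for mean ± SD and a dashed line at 5.92, the median of all probe sets. MDA-MB-231 arrays lay above the line and LCC9 and MCF7 arrays below it, with overlapping ranges of the labels in each line.

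In MDA-MB-231, S100P, FLG, ID2 and CYP1B1 were the genes raised most in the arrays labelled BLID shRNA, and PKIB, GSDME, CLGN and KISS1 were lowered most. S100P, a calcium-binding protein, averaged 10.29 ± 0.07 (log2, SD, n = 4) against 7.96 ± 0.39 in controls, 5.01-fold higher (limma adjusted p = 2.56e-11). FLG, an epidermal filament-binding protein, averaged 8.61 ± 0.08 against 6.30 ± 0.17, 4.94-fold higher (limma adjusted p = 1.02e-13). ID2 and ID3, inhibitors of helix-loop-helix transcription factors, rose by 2.21 and 1.83. CSF1, a macrophage growth factor, averaged 11.35 ± 0.02 against 9.49 ± 0.37, and its other 2 bright probe sets (a line mean of at least 5.92) rose by 0.29 and 0.37 only. PKIB, an inhibitor of protein kinase A, averaged 5.07 ± 0.07 against 7.31 ± 0.84 in its brightest probe set, at least 4.71-fold lower there (limma adjusted p = 3.1e-08). Its other bright probe set fell by 1.18 on the log2 scale. GSDME, a pore-forming gasdermin, averaged 8.68 ± 0.15 against 10.62 ± 0.24, 3.85-fold lower (limma adjusted p = 1.33e-10). The other genes named by rule rose by 1.73 to 2.10 (CYP1B1, TNFSF18, SCG5, CEMIP and COXFA4L3) or fell by 1.55 to 1.90 on the log2 scale (CLGN, KISS1, AOX1, CHRDL1, AKAP12, DTNA, TMEM109 and JPH1). The changes of TNFSF18, PKIB, DTNA and JPH1 are lower bounds for the probe sets used, since 1 of the groups averaged below 5.92. For DTNA, 1 of 5 bright probe sets moved the other way. The effects of all 20 genes differed between the lines, with a largest interaction adjusted p of 0.00113 (SCG5). Of 13580 genes, 4023 changed in MDA-MB-231, 1489 up and 2534 down, and 165 of them changed at least 2-fold (68 up, 97 down). Groups were fully apart for 3109 of the changed genes and for 3733 of all 13580 genes, where chance alone gives 2.857%. The share of changed genes that fell was 63.0% in the deposited scale and 56.3% after quantile normalization.

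The lists of TGF-beta targets, matrix, immediate early and integrin genes were called higher in the MDA-MB-231 arrays labelled BLID shRNA. Of 23 measured TGF-beta targets, 15 rose and 0 fell (17 and 0 when adjusted over the list alone), with a median log2 change of 0.56 (camera adjusted p = 4.98e-11; adjusted p = 0.00314 with an estimated correlation). ID2 and BAMBI, a decoy receptor of the pathway that rose by 0.79, had the smallest adjusted p among them. The list mean was 10.03 against 9.35 (exact permutation p = 0.0286, the smallest possible; adjusted p = 0.0705 over the lists). Of 22 collagens and matrix proteins, 9 rose and 2 fell (10 and 2 when adjusted over the list alone), with a median of 0.29 (camera adjusted p = 0.000329; adjusted p = 0.00314 with an estimated correlation). LAMC1, a laminin chain, rose by 0.95, and COL6A1 rose by 1.56 (0.22 without probe sets marked _s_at or _x_at). Of 31 MAPK feedback and immediate early genes, 13 rose and 1 fell (13 and 1 adjusted over the list alone), with a median of 0.33 (camera adjusted p = 0.00067; adjusted p = 0.0349 with an estimated correlation). HBEGF, an EGF receptor ligand, rose by 1.10 and SPRY4, a feedback inhibitor of the pathway, by 0.91. Of 27 integrins and adhesion genes, 12 rose and 3 fell (12 and 3 adjusted over the list alone), with a median of 0.12 (camera adjusted p = 0.00134; adjusted p = 0.0349 with an estimated correlation). ITGB4 rose by 1.25 and ITGA5, a fibronectin receptor subunit, by 1.00. The least changed bright probe sets of LAMC1 and ITGB4 rose by 0.40 and 0.13.

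The lists of mesenchymal, NF-kB target, lysosomal and stem cell and drug resistance genes were also called higher in the MDA-MB-231 arrays labelled BLID shRNA, with calls that did not hold under an estimated correlation. Of 32 mesenchymal genes and EMT regulators, 13 rose and 4 fell (15 and 5 adjusted over the list alone), with a median of 0.14 (camera adjusted p = 0.00789; adjusted p = 0.102 with an estimated correlation). THBS1, a matrix glycoprotein, rose by 0.74, and it was not called without probe sets marked _s_at or _x_at (0.55, adjusted p = 0.0529). Of 18 NF-kB targets and cytokines, 8 rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 0.21 (camera adjusted p = 0.00789; adjusted p = 0.434 with an estimated correlation). NFKBIA, the inhibitor induced by NF-kB, rose by 0.83 and CXCL2, a neutrophil attractant, by 1.58. Control replicate 3 stood high for this list at a mean of 8.31, and without it the median was 0.38. With all probe sets of a gene averaged, the list was not called (0.16, adjusted p = 0.0765). Of 35 autophagy and lysosome genes, 11 rose and 2 fell (14 and 2 adjusted over the list alone), with a median of 0.16 (camera adjusted p = 0.00646; adjusted p = 0.434 with an estimated correlation). CTSD, a lysosomal protease, rose by 1.29 and SQSTM1, an autophagy receptor, by 0.58 (0.04 in its least changed bright probe set). Without control replicate 4 the lysosomal median was 0.06 (adjusted p = 0.05). Of 22 stem cell and drug resistance genes, 7 rose and 1 fell (7 and 2 adjusted over the list alone), with a median of 0.07 (camera adjusted p = 0.0197; adjusted p = 0.102 with an estimated correlation). ABCC3, an organic anion transporter, rose by 1.46 (0.24 without probe sets marked _s_at or _x_at). Without control replicate 4 the list was not called (0.04, adjusted p = 0.0531), and its median was 0.13 without control replicate 3, 0.02 without control replicate 1, and 0.04 without BLID shRNA replicate 1 or 4.

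Cell cycle and DNA repair genes were lower in the MDA-MB-231 arrays labelled BLID shRNA. Of 38 G2/M genes, 33 fell and 1 rose (35 and 1 adjusted over the list alone), with a median log2 change of -0.43 (camera adjusted p = 5.32e-12; adjusted p = 0.223 with an estimated correlation). BUB1B, a spindle checkpoint kinase, fell by 0.68 and KIF20A, a mitotic kinesin, by 0.81 on the log2 scale. Of 39 G1/S and DNA replication genes, 30 fell and 1 rose (30 and 1 adjusted over the list alone), with a median of -0.41 (camera adjusted p = 4.98e-11; adjusted p = 0.143 with an estimated correlation). CCNE2, cyclin E2, averaged 9.34 ± 0.13 (n = 4) against 10.58 ± 0.13 (limma adjusted p = 7.74e-11), and MCM6, part of the replicative helicase, fell by 0.65 on the log2 scale (0.39 in its other bright probe set). Of 27 DNA repair genes, 16 fell and 0 rose (17 and 0 adjusted over the list alone), with a median of -0.27 (camera adjusted p = 3.54e-05; adjusted p = 0.103 with an estimated correlation). PARP1, which senses strand breaks, fell by 0.82 and BARD1, the partner of BRCA1, by 0.65 on the log2 scale. The mean of each of these 3 lists separated the arrays completely (exact permutation p = 0.0286, the smallest possible; adjusted p = 0.0705 over the lists).

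Lists of mitochondrial, chaperone and ribosomal genes were called lower in MDA-MB-231 by small medians, most of their members did not change, and no call held under an estimated correlation. Of 37 oxidative phosphorylation genes, 12 fell and 0 rose (12 and 0 adjusted over the list alone), with a median of -0.12 (camera adjusted p = 0.00135; adjusted p = 0.434 with an estimated correlation). UQCRC2 and NDUFB9, subunits of the respiratory chain, fell by 0.33 and 0.27 on the log2 scale. Of 28 mitochondrial dynamics and mitophagy genes, 9 fell and 0 rose (9 and 0 adjusted over the list alone), with a median of -0.13 (camera adjusted p = 0.016; adjusted p = 0.434 with an estimated correlation). CLPP, a matrix protease, fell by 0.55 and VDAC3, an outer membrane channel, by 0.43 on the log2 scale. Of 17 heat shock and proteostasis genes, 4 fell and 0 rose (4 and 0 adjusted over the list alone), with a median of -0.22 (camera adjusted p = 0.0166; adjusted p = 0.58 with an estimated correlation). HSPE1 fell by 0.43 and HSP90AA1 by 0.21 on the log2 scale. Of 31 ribosomal protein genes, 12 fell and 0 rose (12 and 0 adjusted over the list alone), with a median of -0.06 (camera adjusted p = 0.00213; adjusted p = 0.434 with an estimated correlation). RPL3 and RPL7 fell by 0.32 and 0.18 on the log2 scale. The least changed bright probe sets of UQCRC2, HSP90AA1 and RPL7 fell by 0.06, 0.14 and 0.12. With all probe sets of a gene averaged, the oxidative phosphorylation list was not called (-0.08, adjusted p = 0.0556).

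In LCC9, interferon-induced genes were raised most in the arrays labelled BLID shRNA, and GJA1, SHISA2 and PDZK1 were lowered most. IFIT1, which binds viral RNA, averaged 10.92 ± 0.25 (log2, SD, n = 4) against 6.04 ± 1.47 in controls, 29.4-fold higher (limma adjusted p = 2.73e-08). IFIT3 averaged 9.38 ± 0.29 against 5.03 ± 0.71 in its brightest probe set, at least 20.4-fold higher there (limma adjusted p = 7.72e-10). RIGI, a sensor of double-stranded RNA, averaged 8.66 ± 0.20 against 6.35 ± 0.29. SAMD9, IFI6, IFIT2, CMPK2, DDX60, OAS1 and XAF1 rose by 2.57 to 3.42. The least changed bright probe sets rose by 1.53 for IFIT3, 1.31 for SAMD9, 1.21 for IFIT2, 0.49 for XAF1 and 0.12 for RIGI. At least 1 group averaged below 5.92 for IFIT3, SAMD9, IFIT2, DDX60, XAF1, SHISA2, LGI1, ADRB1 and ODAM. Their changes are lower bounds for the probe sets used, not for every probe set of the gene. GJA1, the gap junction protein connexin 43, averaged 8.21 ± 0.08 against 10.57 ± 0.17, 5.14-fold lower (limma adjusted p = 4.67e-07). BAX, a pore-forming member of the BCL2 family, averaged 7.38 ± 0.08 against 8.92 ± 0.37, 2.91-fold lower (limma adjusted p = 1.13e-06). SHISA2, PDZK1, LGI1, FGFBP2, AFAP1L2, PRKX, ADRB1 and ODAM fell by 1.55 to 2.19 on the log2 scale. Interaction tests separated the lines for 19 of these 20 genes, with a largest adjusted p of 0.0332 (PRKX), and BAX had 0.0601. Of 13580 genes, 2915 changed in LCC9, 988 up and 1927 down, and 113 changed at least 2-fold (54 up, 59 down). Groups were fully apart for 2730 of the changed genes and for 4279 of all 13580 genes, where chance alone gives 2.857%. The share of changed genes that fell was 66.1% in the deposited scale and 55.4% after quantile normalization.

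Of 35 interferon response genes in LCC9, 29 rose and 1 fell (30 and 1 adjusted over the list alone), with a median log2 change of 1.58 (camera adjusted p = 1.86e-31; adjusted p = 0.104 with an estimated correlation). The list mean was 8.25 against 6.62 (exact permutation p = 0.0286, the smallest possible; adjusted p = 0.0661 over the lists). Of 37 unfolded protein response and ATF4 targets, 18 rose and 2 fell (22 and 4 adjusted over the list alone), with a median of 0.24 (camera adjusted p = 1.86e-09; adjusted p = 0.294 with an estimated correlation). DDIT3, a transcription factor of the stress response, averaged 10.02 ± 0.09 (n = 4) against 8.25 ± 0.03 (limma adjusted p = 7.72e-10). The chaperones DNAJB9 and HSPA5 rose by 1.84 and 0.94 (HSPA5 by 0.57 in its other bright probe set), and ATF3 rose by 2.03. Another probe set stood for ATF3 without LCC9 BLID shRNA replicate 1 (0.47) and without MCF7 BLID shRNA replicate 3 (0.41). Of 27 NRF2 and antioxidant genes, 6 rose and 2 fell (6 and 2 adjusted over the list alone), with a median of 0.10 (camera adjusted p = 0.0437; adjusted p = 0.954 with an estimated correlation). HMOX1, which breaks down heme, rose by 1.21, SLC7A11, the cystine transporter, by 0.97 and GCLC, which makes glutathione, by 0.26 (0.17, adjusted p = 0.111, without probe sets marked _s_at or _x_at). GPX3, an extracellular peroxidase, rose by 1.16 (0.76 in its other bright probe set), and with an RNA quality covariate it was not called (0.49, adjusted p = 0.196). This list was not called after quantile normalization (adjusted p = 0.127), its median was -0.08 with the RNA quality covariate, and it was not called without LCC9 control replicate 1 or 2, LCC9 BLID shRNA replicate 3 or MDA-MB-231 control replicate 1, 3 or 4 (adjusted p = 0.05 to 0.201). Its median was 0.16 without LCC9 control replicate 3 and without LCC9 control replicate 4. Of 31 ribosomal protein genes, 3 fell and 0 rose (3 and 0 adjusted over the list alone), with a median of -0.06 (camera adjusted p = 0.016; adjusted p = 0.954 with an estimated correlation). RPS9, RPL3 and RPS10 fell by 0.45, 0.25 and 0.07 on the log2 scale, and the list was not called after quantile normalization (adjusted p = 0.127) or without control replicate 2 (adjusted p = 0.0698). RPS10 was not called after quantile normalization (adjusted p = 0.105), nor without BLID shRNA replicate 1 or 3 or control replicate 1, 2 or 3 (adjusted p = 0.0561 to 0.0716). The 3′ minus 5′ difference of control probe sets, a sign of RNA quality, averaged 0.95 ± 0.02 (log2, n = 4) in the LCC9 arrays labelled BLID shRNA and 1.19 ± 0.15 in the controls (exact permutation p = 0.0286, adjusted p = 0.0857).

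In MCF7, interferon genes and aldo-keto reductases were raised most in the arrays labelled BLID shRNA, and ANTXR1, SH3BGRL and FRK were lowered most. RSAD2, an antiviral enzyme, averaged 11.61 ± 0.09 (log2, SD, n = 4) against 7.02 ± 1.04 in controls, 24.1-fold higher (limma adjusted p = 3.05e-11). AKR1C2, which reduces steroids and carbonyls, averaged 13.96 ± 0.04 against 9.38 ± 1.18, 23.8-fold higher (limma adjusted p = 3.54e-10). AKR1C1 and AKR1C3 rose by 4.46 and 3.65. Without control replicate 1 the differences were 5.16 for AKR1C2, 4.99 for AKR1C1, 4.30 for AKR1C3 and 5.02 for RSAD2. The near-identical sequences of this family leave open which member each probe set read. IFNL2, an interferon itself, averaged 8.89 ± 0.12 against 5.22 ± 0.35 (limma adjusted p = 2.28e-15), and its probe set may read the close relative IFNL3. IFNL2 in LCC9 averaged 6.55 ± 0.16 (n = 4) against 5.10 ± 0.17, a difference of at least 1.45 (exact permutation p = 0.0286, the smallest possible). IFNB1, interferon beta, was chosen after its values were seen and averaged 7.52 ± 0.13 against 4.20 ± 0.65, a difference of at least 3.32, while both groups of LCC9 and of MDA-MB-231 lay below 5.92. The LCC9 groups of IFNB1 were nonetheless fully apart, higher in the arrays labelled BLID shRNA (exact permutation p = 0.0286, the smallest possible). IFIT2, IFIT3, CMPK2, IFI44L and OASL rose by 2.90 to 4.09. ANTXR1, a collagen-binding receptor, averaged 6.39 ± 0.15 against 8.60 ± 0.96, 4.64-fold lower (limma adjusted p = 3.75e-07), but its other 2 bright probe sets fell by 0.27 and 0.22 only. SH3BGRL, FRK, KCNMA1, HPGD, AFAP1L2, SELENOP, PAQR5, NRXN3 and PDZK1 fell by 1.63 to 2.05 on the log2 scale. The least changed bright probe sets of SH3BGRL, PAQR5 and NRXN3 fell by 1.23, 0.75 and 0.44. The changes of IFNL2, AKR1C3 and SELENOP are lower bounds, since 1 of the groups averaged below 5.92. All 20 genes named by rule differed between the lines, with a largest interaction adjusted p of 0.0182 (SELENOP). Of 13580 genes, 3737 changed in MCF7, 1416 up and 2321 down, and 222 changed at least 2-fold (115 up, 107 down). Groups were fully apart for 2831 of the changed genes and for 3428 of all 13580 genes, where chance alone gives 2.857%. Of the changed genes 62.1% fell in the deposited scale and 55.5% after quantile normalization.

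Interferon, MHC class I and NRF2 genes rose together in the MCF7 arrays labelled BLID shRNA, and each call held under an estimated correlation. Of 35 interferon response genes, 32 rose and 0 fell (32 and 0 adjusted over the list alone), with a median log2 change of 2.10 (camera adjusted p = 4.48e-38; adjusted p = 0.0123 with an estimated correlation). IFI35 rose by 2.10 and ISG15, a ubiquitin-like modifier, by 1.89. The list mean was 11.06 against 8.95 (exact permutation p = 0.0286, the smallest possible; adjusted p = 0.0587 over the lists). Of 18 MHC class I antigen presentation genes, 15 rose and 0 fell (16 and 0 adjusted over the list alone), with a median of 0.87 (camera adjusted p = 8.47e-15; adjusted p = 0.0123 with an estimated correlation). B2M, the light chain of class I molecules, averaged 14.20 ± 0.07 (n = 4) against 13.32 ± 0.14 (limma adjusted p = 9.92e-11). TAP1 and TAP2, the peptide transporter, rose by 1.64 and 1.12 (0.00 in the least changed bright probe set of TAP2), and NLRC5, an activator of class I genes, by at least 1.86 (controls below 5.92). Of 27 NRF2 and antioxidant genes, 21 rose and 1 fell (23 and 1 adjusted over the list alone), with a median of 0.57 (camera adjusted p = 2.89e-17; adjusted p = 0.0123 with an estimated correlation). HMOX1 rose by 2.52, SRXN1, which restores peroxiredoxins, by 1.40 and GCLC by 0.76. Control replicate 1 lay above the other MCF7 controls for ISG15 (12.66) and AKR1C2 (11.14). The 3′ minus 5′ difference of control probe sets averaged 0.99 ± 0.05 (log2, n = 4) against 1.21 ± 0.19 in MCF7 controls (exact permutation p = 0.114). For the GAPDH probe sets alone it was 0.53 ± 0.01 against 0.60 ± 0.03 (exact permutation p = 0.0286, adjusted p = 0.0857).

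The lists of stress, NF-kB and RNA interference genes were also called higher in the MCF7 arrays labelled BLID shRNA, with fewer risers than other members and calls that did not hold under an estimated correlation. Of 37 unfolded protein response and ATF4 targets, 16 rose and 3 fell (18 and 3 adjusted over the list alone), with a median of 0.22 (camera adjusted p = 2.93e-06; adjusted p = 0.315 with an estimated correlation). DDIT3, DNAJB9 and HSPA5 rose by 1.65, 1.38 and 0.72, with 0.08 in the other bright probe set of HSPA5. ATF3, a stress-induced repressor, rose by 1.70, and without MCF7 BLID shRNA replicate 3 another probe set stood for it with 0.30 (adjusted p = 0.0503), as it did with 0.28 without LCC9 BLID shRNA replicate 1. Of 18 NF-kB targets and cytokines, 7 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 0.25 (camera adjusted p = 0.00805; adjusted p = 0.455 with an estimated correlation). CCL5, a lymphocyte attractant, rose by 2.40, TNFAIP3, an inhibitor of the pathway, by 1.69 and NFKBIA by 0.88. With all probe sets of a gene averaged, the list was not called (0.18, adjusted p = 0.076). Of 16 RNA interference machinery genes, 6 rose and 2 fell (7 and 2 adjusted over the list alone), with a median of 0.12 (camera adjusted p = 0.0462; adjusted p = 0.315 with an estimated correlation). TLR3 rose by at least 1.80 (controls below 5.92), EIF2AK2 by 0.90 (0.52 in its least changed bright probe set) and ADAR by 0.62. All of these act on double-stranded RNA, and they had the smallest adjusted p of the list. Its call is therefore not read as a change of RNA interference as such. DICER1, which cuts small RNA precursors, came next and rose by 0.47. The list was not called after quantile normalization (adjusted p = 0.0511) or with a block for replicate number (adjusted p = 0.0712). Leaving out single arrays also ended its call (adjusted p = 0.0535 to 0.107): MCF7 BLID shRNA replicates 1 and 4, MCF7 control replicates 2 and 4, MDA-MB-231 BLID shRNA replicates 2 and 3, MDA-MB-231 control replicates 1, 2 and 4, LCC9 BLID shRNA replicate 2, and LCC9 control replicates 1 and 3. DICER1 was not called in MCF7 without MCF7 control replicate 2, where another probe set stood for it with 0.23 (adjusted p = 0.195), nor without MCF7 BLID shRNA replicate 1 or 4, MDA-MB-231 BLID shRNA replicate 2, MDA-MB-231 control replicate 2 or LCC9 control replicate 3 (0.36 to 0.39, adjusted p = 0.05 to 0.0925).

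**Figure D2:**
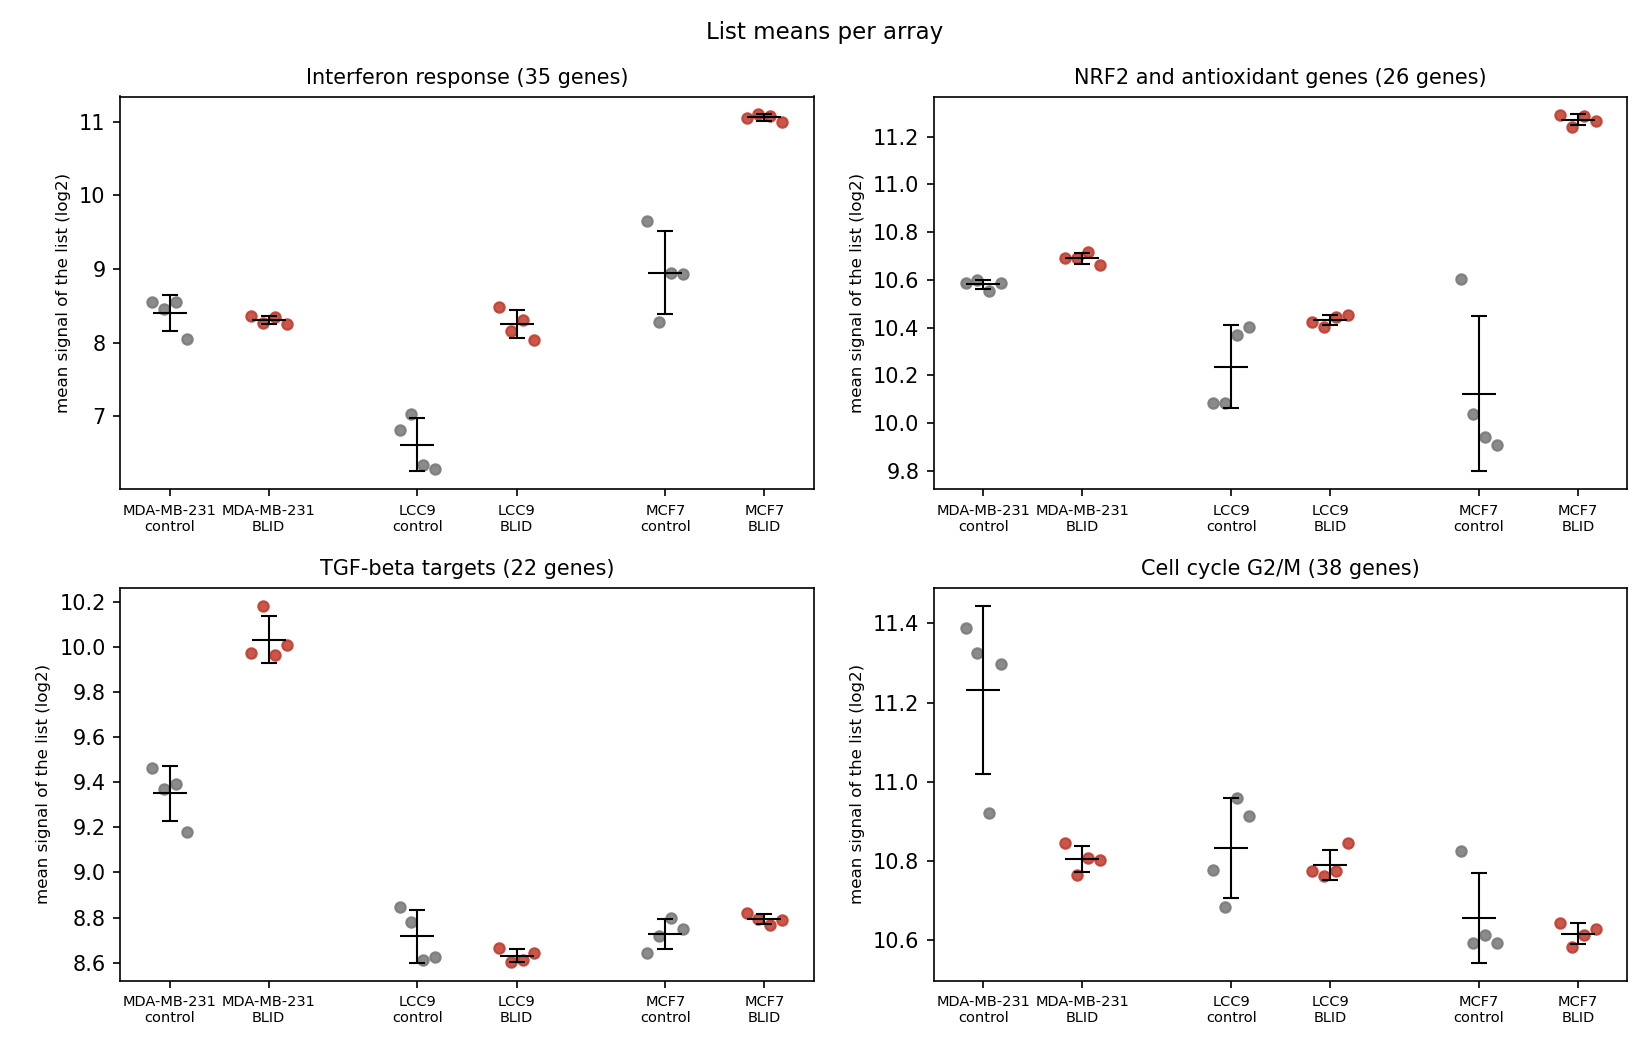
Mean log2 signal of the interferon response, NRF2, TGF-beta target and G2/M lists on each array (vertical axis) by cell line and shRNA label, with points for arrays and bars for mean ± SD. Interferon means rose with the BLID shRNA label in LCC9 and MCF7, NRF2 means in MCF7, and MDA-MB-231 showed higher TGF-beta target and lower G2/M means.

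The interferon list was called in LCC9 (adjusted p = 0.104 with an estimated correlation) and in MCF7 (adjusted p = 0.0123 with an estimated correlation). In MDA-MB-231 1 of its 35 genes rose and 4 fell, with a median of -0.04 (camera adjusted p = 1). IFIT1 averaged 10.86 ± 0.25 (n = 4) against 10.89 ± 0.22 in MDA-MB-231. Control means of the interferon list were 8.40 in MDA-MB-231, 6.62 in LCC9 and 8.95 in MCF7. The median effect on the interferon list was 1.69 larger in LCC9 than in MDA-MB-231 (camera adjusted p = 4.69e-19; adjusted p = 0.143 with an estimated correlation) and 2.18 larger in MCF7 than in MDA-MB-231 (camera adjusted p = 7.19e-26; adjusted p = 0.0625 with an estimated correlation). MHC class I genes responded more in MCF7 than in LCC9 by 0.84 (adjusted p = 3e-16; adjusted p = 0.0165 with an estimated correlation), and NRF2 genes by 0.45 (adjusted p = 3e-16; adjusted p = 0.0223 with an estimated correlation). The effect on G2/M genes was higher than in MDA-MB-231 by a median of 0.37 in LCC9 (adjusted p = 5.7e-09; adjusted p = 0.388 with an estimated correlation) and 0.39 in MCF7 (adjusted p = 4.04e-08; adjusted p = 0.417 with an estimated correlation). The G2/M list mean itself changed by -0.04 in LCC9 and -0.04 in MCF7. With the RNA quality covariate the G2/M list was also called lower in LCC9 (-0.21, adjusted p = 0.000177) and MCF7 (-0.15, adjusted p = 0.00148). It was called lower in LCC9 without the 4 arrays with the largest 3′ minus 5′ difference too (-0.16, adjusted p = 0.0213). The effect on TGF-beta targets was lower than in MDA-MB-231, with median differences of -0.65 for LCC9 (adjusted p = 3.53e-09; adjusted p = 0.0103 with an estimated correlation) and -0.51 for MCF7 (adjusted p = 1.98e-05; adjusted p = 0.0734 with an estimated correlation). The TGF-beta list mean itself changed by -0.09 in LCC9 (exact permutation p = 0.314) and 0.07 in MCF7 (exact permutation p = 0.114). CBR3, a carbonyl reductase, fell by 0.93 on the log2 scale in MDA-MB-231 and rose by 1.18 in MCF7 (interaction adjusted p = 5.94e-10). RHOBTB3, TRIM56 and EIF4EBP2 also changed in opposite directions, with effects of 0.90, -0.31 and 0.58 in MDA-MB-231 and -1.09, 0.86 and -0.65 in MCF7. RNF213, an interferon-inducible ubiquitin ligase, rose by 1.53 in MCF7, and its change of -0.34 in LCC9 was not called after quantile normalization (adjusted p = 0.0516) or without LCC9 control replicate 3 (adjusted p = 0.0696) or 4 (adjusted p = 0.0569). With all probe sets of a gene averaged, EIF4EBP2 in MCF7 (-0.29, adjusted p = 0.142) and TRIM56 in MDA-MB-231 (-0.18, adjusted p = 0.0615) were not called. Effects differed between lines for 4266 of 13580 genes by the interaction test, and 661 genes changed in opposite directions in at least 2 lines. The effect differed between MCF7 and MDA-MB-231 for 3646 genes, between LCC9 and MDA-MB-231 for 2964 and between MCF7 and LCC9 for 941.

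PRKX, JDP2, CASK, CSRP2, GANAB, KCNS3 and BAX were lower in the arrays labelled BLID shRNA of all 3 lines, and CXCL8 and AGR2 were higher. PRKX, a protein kinase, fell by at least 1.19 in MDA-MB-231, 1.59 in LCC9 and at least 1.10 in MCF7 on the log2 scale. JDP2, a repressor of AP-1, fell by 1.25, 0.98 and 1.13 in the same order, and BAX by 0.84, 1.54 and 0.90. CASK, CSRP2, GANAB and KCNS3 fell by 0.86 to 1.39 on the log2 scale in every line. NUP58, a nuclear pore protein, was higher by 0.93, 1.19 and 1.02 in its brightest probe set. Its other 3 bright probe sets had differences of -0.39, -0.29 and -0.10 in MDA-MB-231, -0.12, 0.12 and 0.21 in LCC9, and -0.04, 0.35 and 0.49 in MCF7. AGR2, a protein disulfide isomerase, rose by 0.85, 2.17 and 1.48, and in MDA-MB-231 it was not called without control replicate 4 (0.63, adjusted p = 0.0616). CXCL8, a neutrophil attractant, rose by 1.68, at least 1.77 and at least 2.86 in its brightest probe set, with overlapping groups in MDA-MB-231. CXCL8 rose by 1.38, 0.59 and 0.80 in its other bright probe set. Its MDA-MB-231 difference was 2.54 without control replicate 3 and was not called without control replicate 4 (1.36, adjusted p = 0.0506), and its LCC9 difference was not called with both probe sets averaged (1.18, adjusted p = 0.144). DICER1 rose by 0.94, 0.58 and 0.47 (interaction adjusted p = 0.000953). In all 3 lines 515 genes changed in the same direction, 119 up and 396 down.

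LCC9 and MCF7 had more genes changed in the same direction than either had with MDA-MB-231, and every pair had more than independent changes would give. LCC9 and MCF7 had 454 genes raised in both, where independent changes would give 103, and 1007 lowered in both, where they would give 329. Opposite changes in these lines numbered 76, against 370 for independent changes. MDA-MB-231 and LCC9 had 215 raised in both (108 if independent), 636 lowered in both (360) and 317 opposite (396). MDA-MB-231 and MCF7 had 274 raised in both (155 if independent), 724 lowered in both (433) and 424 opposite (519). The mean 3′ minus 5′ difference of control probe sets was lower in the arrays labelled BLID shRNA of every line. It was 0.78 against 0.93 in MDA-MB-231 (exact permutation p = 0.114), 0.95 against 1.19 in LCC9 and 0.99 against 1.21 in MCF7. Part of these overlaps and of the genes shared by all 3 lines may therefore go with RNA quality. Across 13580 genes, which are not independent replicates, the effects in LCC9 and MCF7 correlated with Pearson's r = 0.573 and Spearman's rho = 0.501 (array permutation p = 0.0286 for each, the smallest possible; adjusted p = 0.0857 over 3 pairs). The highest r of any other assignment of these arrays was 0.547. For MDA-MB-231 and LCC9 r was 0.176 and rho 0.178 (permutation p = 0.171 for each, adjusted p = 0.171), and for MDA-MB-231 and MCF7 r was 0.147 and rho 0.144 (permutation p = 0.171 for each, adjusted p = 0.171).

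BCL2 family members, caspases and p53 targets were not called as lists in any line. Of 21 BCL2 family genes, 3 rose and 4 fell in MDA-MB-231 (camera adjusted p = 0.978), 2 and 4 in LCC9 (0.638), and 3 and 4 in MCF7 (0.642). Of 24 caspases and apoptosis execution genes, 3 rose and 6 fell in MDA-MB-231, 3 and 4 in LCC9, and 5 and 4 in MCF7, with a smallest camera adjusted p of 0.355. Of 24 p53 targets, 4 rose and 7 fell in MDA-MB-231, 6 and 3 in LCC9, and 7 and 7 in MCF7 (smallest 0.492). Estrogen receptor targets had a median change of 0.09 in MDA-MB-231, -0.09 in LCC9 and 0.03 in MCF7, with 0.0858 in MDA-MB-231 as the smallest adjusted p of their 35 genes and 0.00428 there without control replicate 3. Luminal lineage genes had 2 rises and 11 falls among 26 in MCF7 (adjusted p = 0.0949, and 0.0229 without control replicate 1), and the basal B markers 0 rises and 8 falls among 24 there (0.357). Cholesterol synthesis and uptake genes had 0 rises and 9 falls among 19 in MDA-MB-231 (0.073). That list was called without a filter (adjusted p = 0.0134), with averaged probe sets (adjusted p = 0.0143), with a block for replicate number (adjusted p = 0.049), and without BLID shRNA replicate 3 or 4 or control replicate 1, 2 or 4 of that line (adjusted p = 0.0271 to 0.0459). The smallest camera adjusted p over the 3 lines was 0.382 for epithelial junction and keratin genes, 0.492 for hypoxia and glycolysis, 0.263 for fatty acid synthesis and lipid storage, 0.37 for YAP and TEAD targets, 0.249 for the PI3K-AKT-mTOR pathway and 0.149 for the BLID chromosome 11q24 neighbourhood, which was called in MDA-MB-231 without a filter (0.14, adjusted p = 0.0202). For the marker genes of other cell types it was 0.494 for fibroblasts, 0.432 for blood cells, 0.494 for endothelial cells and 0.323 for melanoma and neural cells. The means of melanoma and neural markers were fully apart in MCF7 (-0.29) and LCC9 (-0.14), as were those of fibroblast markers in MCF7 (-0.23), each with exact permutation p = 0.0286, the smallest possible (adjusted p = 0.0587 in MCF7 and 0.0661 in LCC9). Means were also fully apart in LCC9 for the BCL2 family (-0.14), estrogen receptor targets (-0.14), hypoxia and glycolysis (-0.10), PI3K-AKT-mTOR (-0.11), epithelial (-0.09), luminal (0.08), basal B (-0.16), mesenchymal (-0.13), collagen (-0.18), oxidative phosphorylation (-0.09), MHC class I (0.09) and NF-kB genes (0.08). In MCF7 they were apart for epithelial (-0.13), luminal (-0.19), basal B (-0.16), mesenchymal (-0.15), collagen (-0.15), integrin (-0.20), oxidative phosphorylation (-0.08), DNA repair (-0.07), ribosomal (-0.06) and MAPK genes (0.17). In MDA-MB-231 they were apart for PI3K-AKT-mTOR (0.09), basal B (0.10) and NRF2 genes (0.11), none of them called there. By fry, which tests a list without reference to other genes, calls were added for melanoma and neural (adjusted p = 0.000924), luminal (adjusted p = 0.0126), PI3K-AKT-mTOR (adjusted p = 0.00988) and basal B genes (adjusted p = 0.00153) in MCF7. Others in MCF7 were integrin (adjusted p = 0.000288) and mesenchymal genes (adjusted p = 0.00988), lower where MDA-MB-231 had them higher, and ribosomal (adjusted p = 0.00866), MAPK (adjusted p = 0.0186) and stem cell genes (adjusted p = 0.0358). In LCC9 fry added collagens (lower, adjusted p = 0.00932), MAPK (adjusted p = 0.0329), basal B (adjusted p = 0.00932), fatty acid (adjusted p = 0.0329) and PI3K-AKT-mTOR genes (adjusted p = 0.0426). Basal B markers were also called in MDA-MB-231 with averaged probe sets (0.14, adjusted p = 0.0476), and luminal genes in LCC9 with the RNA quality covariate (0.12, adjusted p = 0.0262). Counts adjusted over the list alone differed from these by at most 3 genes.

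**Figure D3:**
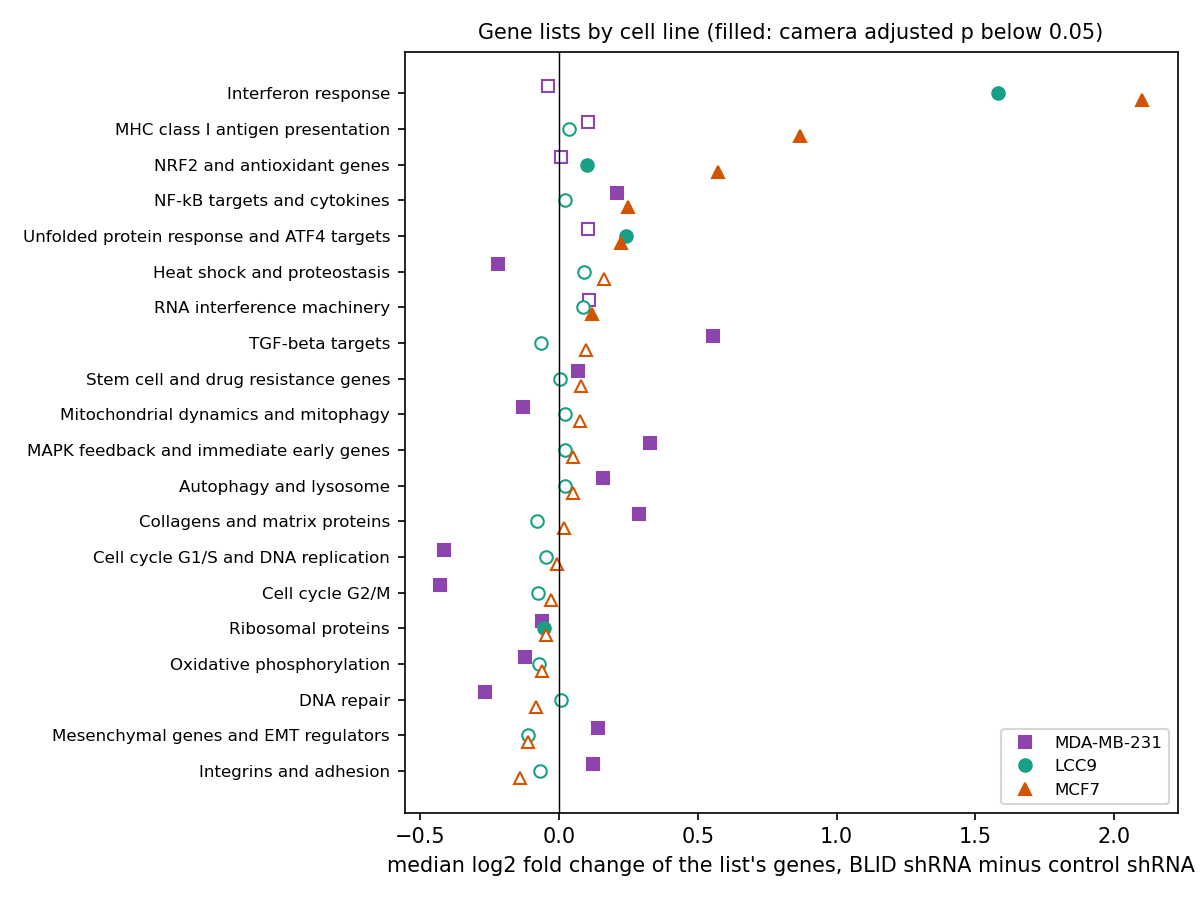
Median log2 change (BLID shRNA minus control shRNA, horizontal axis) of 20 gene lists in each cell line, with filled points where the camera adjusted p was below 0.05. Interferon response genes stood farthest to the right in MCF7 (2.10) and LCC9 (1.58), and G2/M genes farthest to the left in MDA-MB-231 (-0.43).

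Control shRNA arrays of MDA-MB-231 and MCF7 differed along the line between mesenchymal and luminal cells, in different media. SRGN, a proteoglycan of basal B lines, averaged 12.47 ± 0.12 (log2, SD, n = 4) in MDA-MB-231 and 4.17 ± 0.10 in MCF7. VIM, the filament protein vimentin, averaged 14.94 ± 0.04 against 8.35 ± 0.21, and MSN, moesin, 11.97 ± 0.17 against 3.71 ± 0.15. EPCAM, an epithelial adhesion molecule, averaged 9.46 ± 0.20 against 13.23 ± 0.14, KRT8 11.44 ± 0.11 against 14.18 ± 0.14 and TFAP2C 8.15 ± 0.37 against 12.21 ± 0.06. The estrogen receptor targets RERG, XBP1 and PGR had log2 differences of -5.98, -3.26 and -5.72 in MDA-MB-231, where RERG and PGR lay below 5.92. Of 24 basal B markers 22 were higher (median 5.56, camera adjusted p = 1.66e-15), of 32 mesenchymal genes 29 were higher (4.37, 7.79e-17) and of 26 YAP and TEAD targets 25 were higher (2.69, 3.85e-14). Of 37 epithelial genes 33 were lower (-2.43, 7.05e-10), of 26 luminal genes 24 were lower (-2.81, 1.43e-09) and of 35 estrogen receptor targets 28 were lower (-2.43, 9.05e-06; adjusted p = 0.0599 with an estimated correlation). MAPK (1.63), integrin (1.23), collagen (0.92) and hypoxia genes (0.85) were higher as lists as well, with adjusted p of 3.44e-06, 9.21e-05, 0.000222 and 7.48e-07. MHC class I (0.97, 0.000204), G2/M (0.57, 1.28e-05), stem cell (0.19, 0.0419) and chromosome 11q24 genes (0.85, 0.019) were higher too, with adjusted p = 0.281, 0.592, 0.0963 and 0.133 with an estimated correlation. In all, 9627 of 13580 genes differed, 4306 higher and 5321 lower, of which 3439 differed at least 2-fold (1683 higher, 1756 lower). The median difference of all tested genes was -0.08 in the deposited scale and -0.10 after quantile normalization.

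LCC9 control arrays held interferon genes at lower levels than MCF7 control arrays, in another medium. The list mean was 9.66 in MCF7 control replicate 1, 8.29 to 8.94 in the other MCF7 controls and 6.28 to 7.03 in LCC9 controls, so replicate 1 raised the difference. Of 35 interferon response genes 31 were lower and 0 higher, with a median log2 difference of -1.91 (camera adjusted p = 4.75e-26; adjusted p = 0.122 with an estimated correlation). MHC class I genes were lower with 10 of 18 (-0.38, 0.0027; adjusted p = 0.628 with an estimated correlation) and estrogen receptor targets with 15 of 35 (-0.20, 0.0107; adjusted p = 0.607 with an estimated correlation). PGR, the progesterone receptor, averaged 8.66 ± 0.24 (log2, SD, n = 4) in LCC9 and 10.42 ± 0.18 in MCF7, and CELSR2 and OLFM1 were lower by 1.57 and 2.13 on the log2 scale. ERBB4, a receptor tyrosine kinase of luminal cells, averaged 8.48 ± 0.26 against 5.50 ± 0.76. KRT8 and MLPH were lower by 0.55 and 0.58 on the log2 scale, and the basal B markers IGF2BP2 and CD44 were higher by 1.10 and 0.66, while ANXA1 lay below 5.92 in both lines. Oxidative phosphorylation genes were higher with 20 of 37 (0.16, 0.000327), fatty acid genes with 11 of 22 (0.22, 0.000682), collagens with 7 of 22 (0.10, 0.0107) and G2/M genes with 16 of 38 (0.17, 0.0107), and unfolded protein response genes were lower with 10 of 37 (-0.14, 0.0498). With an estimated correlation these 5 had adjusted p = 0.607, 0.206, 0.117, 0.843 and 0.843. Luminal genes (-0.12) and basal B markers (0.11) were not called, each with an adjusted p of 0.114. In all, 4696 of 13580 genes differed, 2527 higher and 2169 lower, and 460 differed at least 2-fold (236 higher, 224 lower).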

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

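The tests of the BLID signal against background, of MIR100HG and of MCF7 control replicate 1 were chosen only after the result was seen. The covariate for RNA quality and the other splits of the arrays were planned. Reading the covariate on the interferon genes of LCC9 and MCF7 follows from the rise found there.

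Interferon response genes were higher in the arrays labelled BLID shRNA of LCC9 and MCF7, while the 3′ minus 5′ difference of control probe sets was lower there. With that difference as a covariate the median of the 35 interferon genes was 1.26 in LCC9 (27 higher and 1 lower, camera adjusted p = 3.16e-31) and 2.09 in MCF7 (32 higher and 0 lower, camera adjusted p = 1.17e-42). The median absolute deviation of the members was 1.48 and 0.73. In MCF7 this argues against RNA quality as the whole cause, although only control replicate 1 reached the range of the arrays labelled BLID shRNA. In LCC9 the test cannot decide. The 3′ minus 5′ difference there was 0.93 to 0.98 on the arrays labelled BLID shRNA and 1.01 to 1.36 on the controls. Without overlap, the fit rests on a slope taken within the groups of all lines. The fit had medians of 1.58 and 2.10 without the covariate, so some or all of the LCC9 rise may go with RNA quality. In that fit the LCC9 call did not hold under an estimated correlation. A response to the shRNA construct, to clone or culture differences and to loss of BLID stay open, because each line carried 1 BLID shRNA clone and no loss of BLID was measured.

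No lower BLID signal passed a test in any line. A mean of 21.9% of probe sets was dimmer than BLID in LCC9 controls (17.8 to 26.5 over 4 arrays) and 20.7% in MCF7 controls (17.1 to 24.96), so a signal at background is consistent with the missing difference in these lines. In MDA-MB-231 controls 67.8% of probe sets were dimmer (62.4 to 76.0), which argues against background there. Reading of MIR100HG transcripts by the BLID probe set stays open: over 7 MDA-MB-231 arrays the signals correlated with r = 0.805 (exact permutation p = 0.0272) and rho = 0.536 (p = 0.236), but r was -0.12 without the 2 arrays farthest from the median. Reduced translation or another transcript end was not measured.

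MCF7 control replicate 1 lay between the groups for interferon genes and stood apart for 8 genes of the text. If RNA from BLID shRNA cells had entered that sample, 23 interferon genes would imply a median share of 17.9% (quartiles 12.7 to 21.6) and 13 other raised genes 14.3% (10.8 to 24.4), with 0 of the 13 below 0. Shares of single genes ran from 6.43% (OAS2) to 45.3% (IFI44) among the former and from 3.15% (IFNL2) to 46.7% (GBP1) among the latter. Mixing alone would give every gene the same share, apart from noise, and genes lowered in the arrays labelled BLID shRNA were not tested as a set. A mixed sample may account for part of the rise. Of the 13 genes 7 are induced by interferon too, so a partial response in that culture alone stays open. The rest (AKR1C1, AKR1C2, AKR1C3, HMOX1, GPX2 and OSGIN1) implied shares of 10.7 to 27.1%, so such a response would have to include them. Mixing does not account for PDZK1, which was highest in this array (12.21) although it fell by 1.63 on the log2 scale in the arrays labelled BLID shRNA. The array's 3′ minus 5′ difference was 0.97, within the 0.93 to 1.41 of the other 7 MCF7 arrays. That range spans both groups: the other controls lay at 1.18 to 1.41 and the arrays labelled BLID shRNA at 0.93 to 1.04. Since the array stood with the latter, the test cannot decide on RNA quality. Leaving the array out kept the interferon list called in MCF7.

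Other splits of the arrays gave fewer changed genes than the real split. Of 35 splits per line, only the real split reached the real count in MDA-MB-231 (4023 genes, highest other 579), in LCC9 (2915, highest other 1) and in MCF7 (3737, highest other 731). This is the smallest share that 35 splits can give. The other splits carry the real difference in their spread, which lowers their counts by construction. They cannot tell the shRNA from differences between cultures or infections. The baseline counts were also reached by 1 of 35 splits, for MDA-MB-231 against MCF7 (9627, highest other 2758) and for LCC9 against MCF7 (4696, highest other 1043). Of 100 splits, 1 reached the 4266 genes that differed between lines (highest other 1687) and 1 the 515 genes shared by all lines (highest other 0). For the number of called lists chance cannot be excluded: 6 of 35 splits reached 15 lists in MDA-MB-231 (highest other 21), 19 of 35 reached 4 in LCC9 (highest other 9) and 11 of 35 reached 6 in MCF7 (highest other 12). The cause of the splits with more lists was not tested.

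Single arrays stood far from the other 3 of their group in 34 of 382 gap tests, of which chance gives about 1 in 20. MDA-MB-231 control replicate 3 was highest for CXCL8 (10.41), NFKBIA (10.82) and the NF-kB list mean (8.31), and lowest for CCNE2 (10.38), HSPE1 (11.65), BARD1 (9.35) and the heat shock list mean (10.44). BLID shRNA replicate 2 of that line was lowest for CXCL8 (8.19), CXCL2 (7.66), NFKBIA (10.91), JDP2 (6.14) and TMEM109 (8.65), and highest for ID2 (9.67). Control replicate 4 was lowest for S100P (7.38) and RNF213 (8.43), and BLID shRNA replicate 4 highest for RPL3 (13.51). MCF7 control replicate 1 was highest for PDZK1 (12.21), AKR1C2 (11.14), AKR1C3 (6.88), DDIT3 (8.98), ISG15 (12.66), CCL5 (7.78), SRXN1 (10.56) and CBR3 (9.64). Other MCF7 arrays stood low for NRXN3 (8.56, control replicate 2), DNAJB9 (11.20, BLID shRNA replicate 1), ANTXR1 (6.17, BLID shRNA replicate 3) and TAP1 (11.10, BLID shRNA replicate 4). BLID shRNA replicate 2 of MCF7 was highest for TLR3 (6.55) and EIF2AK2 (10.91). In LCC9, control replicate 4 was highest for AGR2 (8.30), control replicate 1 for the unfolded protein response list mean (9.98) and BLID shRNA replicate 4 for KCNS3 (8.39), while the last array was lowest for BLID (4.19).

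The effects on several gene lists differed between lines by a test of the difference itself. Relative to MDA-MB-231, the LCC9 effect was higher by a median of 1.69 for interferon, 0.37 for G2/M, 0.35 for G1/S, 0.33 for unfolded protein response, 0.29 for DNA repair and 0.16 for mitochondrial dynamics genes. Differences below 0 were -0.65 for TGF-beta targets, -0.38 for mesenchymal, -0.37 for collagen, -0.27 for integrin and -0.23 for stem cell genes. The MCF7 effect exceeded that in MDA-MB-231 by 2.18 for interferon, 0.93 for MHC class I, 0.64 for NRF2, 0.40 for G1/S, 0.39 for G2/M and 0.35 for heat shock genes. Smaller excesses were 0.24 for unfolded protein response, 0.23 for DNA repair and 0.17 for mitochondrial dynamics genes. Differences below 0 were -0.51 for TGF-beta targets, -0.48 for mesenchymal, -0.46 for integrin and -0.35 for collagen genes. The integrin median was -0.14 in MCF7 against 0.12 in MDA-MB-231. Between MCF7 and LCC9 the differences were 0.84 for MHC class I, 0.78 for interferon, 0.45 for NRF2, 0.34 for NF-kB and -0.19 for luminal genes. The luminal difference had an adjusted p of 0.000612, and 0.398 with an estimated correlation. With an estimated correlation, an adjusted p below 0.05 was kept by the TGF-beta and collagen differences between LCC9 and MDA-MB-231, the collagen and integrin differences between MCF7 and MDA-MB-231, and the MHC class I and NRF2 differences between MCF7 and LCC9.

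The effects of 103 of 118 genes in the text differed between lines, against 4266 of all 13580 genes. The named genes were chosen from the same data by their changes, so a high share is built in, as for the genes named per line. Ranges are the largest minus the smallest log2 change over the 3 lines, groups below 5.92 included. They are therefore not exact for genes with a group below 5.92. Interferon, antigen presentation and cytokine genes ranged by 4.90 for IFIT1, 4.80 for RSAD2, 4.42 for IFIT3, 4.33 for IFIT2, 3.90 for CMPK2, 3.64 for IFNL2, 3.47 for IFI44L, 3.32 for SAMD9, 2.95 for OASL and 2.89 for IFI6. Smaller ranges in this group were 2.81 for DDX60, 2.50 for XAF1, 2.38 for RIGI, 2.30 for CCL5, 2.29 for ISG15, 2.27 for OAS1, 1.97 for IFI35, 1.88 for RNF213, 1.66 for TLR3 and 1.61 for TAP1. The lowest were 1.53 for TNFAIP3, 1.50 for NLRC5, 1.39 for TAP2, 1.21 for CXCL2, 1.17 for TRIM56, 1.04 for EIF2AK2, 1.03 for NFKBIA, 0.80 for B2M and 0.54 for ADAR. Stress and antioxidant genes ranged by 4.18 for AKR1C2, 4.02 for AKR1C1, 3.88 for AKR1C3, 2.13 for ATF3, 2.11 for CBR3, 2.10 for HMOX1, 1.91 for DDIT3, 1.37 for SLC7A11, 1.32 for AGR2 and 1.24 for SRXN1. Below these came 1.10 for DNAJB9, 0.72 for HSPA5, 0.64 for GCLC, 0.57 for HSPE1 and 0.30 for HSP90AA1. Matrix, adhesion and signalling genes ranged by 1.85 for COL6A1, 1.65 for ITGB4, 1.30 for LAMC1, 1.26 for CTSD, 1.21 for ABCC3, 0.95 for ITGA5, 0.87 for SPRY4, 0.85 for BAMBI, 0.71 for HBEGF and 0.68 for SQSTM1. Cell cycle, repair, mitochondrial and RNA genes ranged by 1.12 for CCNE2, 0.64 for KIF20A, 0.64 for MCM6, 0.53 for BARD1, 0.48 for DICER1, 0.46 for BUB1B, 0.46 for VDAC3, 0.45 for PARP1, 0.30 for NDUFB9 and 0.17 for RPL7. Genes changed most in MDA-MB-231 ranged by 2.36 for ID3, 2.35 for AOX1, 2.35 for PKIB, 2.31 for FLG, 2.28 for ID2, 2.10 for S100P, 2.03 for CHRDL1, 1.99 for CLGN, 1.98 for TNFSF18 and 1.95 for GSDME. Others of these genes ranged by 1.82 for COXFA4L3, 1.80 for SCG5, 1.80 for CEMIP, 1.79 for KISS1, 1.67 for AKAP12, 1.67 for CSF1, 1.51 for CYP1B1, 1.39 for JPH1, 1.27 for DTNA and 1.09 for TMEM109. The remaining genes changed most in LCC9 or MCF7, or in opposite directions, ranged by 2.44 for FRK, 2.28 for SH3BGRL, 2.27 for AFAP1L2, 2.20 for KCNMA1, 2.16 for FGFBP2, 2.09 for SHISA2, 1.99 for RHOBTB3, 1.96 for HPGD, 1.85 for NRXN3 and 1.84 for LGI1. The last of them ranged by 1.83 for PDZK1, 1.79 for ODAM, 1.78 for SELENOP, 1.71 for GJA1, 1.64 for ANTXR1, 1.64 for PAQR5, 1.23 for EIF4EBP2, 1.19 for ADRB1 and 0.49 for PRKX.

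Among 4890 probe sets with several or no gene symbols that passed the filter, 26 changed at least 2-fold in MDA-MB-231, 22 in LCC9 and 42 in MCF7 at an adjusted p below 0.05. They lie outside the comparisons between genes, and the platform table does not pair them with a single gene.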

How the results depend on the processing

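The alternatives chosen only after the data were seen were the run of equal values kept, the fits without the 4 arrays with the largest 3′ minus 5′ difference, and the correlation without interferon and MHC genes. Differences past a threshold in the deposited values kept their direction under the alternatives run, except the list and genes named as reversed and the median of the NRF2 and antioxidant genes list in LCC9 without the 4 arrays (-0.03). The MAPK feedback and immediate early genes list in LCC9 (0.02, not called) was called with the RNA quality covariate (0.11, adjusted p = 0.0184), without the 4 arrays (0.11, adjusted p = 0.00778), with fry (adjusted p = 0.0329), without control replicate 1 (0.09, adjusted p = 0.046) and without BLID shRNA replicate 4 (-0.0081, past 0, adjusted p = 0.0475). In MCF7 (0.05, not called) it was called with the covariate (0.13, adjusted p = 0.0103), without the 4 arrays (0.12, adjusted p = 0.0248), with fry (adjusted p = 0.0186) and without control replicate 3 (0.09, adjusted p = 0.0447). Effects past no threshold under either setting were counted as unchanged even where they crossed 0, as BLID did in MCF7. A pseudocount was not applied because the values are log2, and the replicate block was not run for correlations.

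BLID in MDA-MB-231 (0.38) passed limma's unadjusted threshold, again higher in the arrays labelled BLID shRNA, after quantile normalization over all arrays (0.41) or within the line (0.41), with array weights (0.51) and with the RNA quality covariate (0.48). The correlation between LCC9 and MCF7 effects (0.573) was 0.541 with the covariate (permutation p = 0.114) and 0.512 without the 4 arrays (permutation p = 0.0667). Without the interferon and MHC class I list genes it was 0.527 (permutation p = 0.0286). Counting only 2-fold changes gave 165 genes in MDA-MB-231, 113 in LCC9, 222 in MCF7, 3439 for MDA-MB-231 against MCF7, 460 for LCC9 against MCF7, 558 between lines and 2 in all 3 lines. Testing every probe set gave 7004, 5242, 7242, 20430, 8973, 7428 and 799 probe sets in that order, since more are tested. Array weights gave 5451 genes in LCC9, 6477 in MCF7, 7261 between lines and 923 in all 3 lines. Fitting only the 8 arrays compared gave 3514 genes in MDA-MB-231, 4250 in LCC9 and 2736 in MCF7. LCC9 then had the most changed genes and MCF7 the fewest, so the order of the lines depends on the pooled spread. Called lists fell from 15 to 4 in MDA-MB-231, 4 to 0 in LCC9 and 6 to 3 in MCF7 with an estimated correlation, which widens the test by construction. In LCC9 they were 2 after quantile normalization, 2 with averaged probe sets, 2 with the run kept, 7 with the covariate and 8 with fry, and in MCF7 15 with fry. Reversed were ITGB1 in MDA-MB-231 (0.41, -0.31 with averaged probe sets), RPS9 in MDA-MB-231 (-0.31, 0.53 with averaged probe sets), MFN2 in MDA-MB-231 (-0.55, 0.14 without probe sets marked _s_at or _x_at) and the NRF2 list in LCC9 (0.10, -0.079 with the covariate), none past the threshold afterwards. All 3 bright probe sets of ITGB1 rose and the 2 of RPS9 fell in MDA-MB-231. Averaged values in that line may therefore reflect the missing entries of BLID shRNA replicate 1. Except where named, the cause was not tested.

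Leaving out single arrays gave 3361 to 4404 genes in MDA-MB-231, 2268 to 3302 in LCC9, 3080 to 4256 in MCF7, 427 to 619 in all 3 lines, 3856 to 4985 between lines, 9286 to 9684 for MDA-MB-231 against MCF7 and 4187 to 4941 for LCC9 against MCF7. Called lists ranged from 14 to 17, 2 to 5 and 5 to 8. BLID differences ranged from 0.21 to 0.66, 0.02 to 0.18 and -0.11 to 0.04, and correlations from 0.541 to 0.584 (LCC9 and MCF7, permutation p = 0.0571 without each MCF7 control), 0.148 to 0.203 (MDA-MB-231 and LCC9) and 0.114 to 0.168 (MDA-MB-231 and MCF7). Without LCC9 control replicate 2 the lists called there fell to 2. Without MCF7 control replicate 1 the heat shock list was called in MCF7 (adjusted p = 0.0072), and without MDA-MB-231 control replicate 3 the unfolded protein response list was called in that line (adjusted p = 0.0328).

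Replicate numbers did not pair the arrays: residual correlations between arrays of the same number were -0.24 to 0.19. With a block for replicate number 3767 genes changed in MDA-MB-231, 2636 in LCC9 and 3497 in MCF7, and the RNA interference list in MCF7 (adjusted p = 0.0712) and RPS10 in LCC9 (adjusted p = 0.0571) were not called, while the cholesterol list in MDA-MB-231 was called (-0.13, adjusted p = 0.049).

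Of the values for single genes under the other alternatives, 2375 kept their direction and side of the threshold, 34 lost the call, 2 gained it and 3 reversed. For lists these counts were 1137, 44, 36 and 1. With single arrays left out, 4965 gene values were unchanged and 20 lost the call, and 2630 list values were unchanged, 21 lost and 13 gained the call. For arrays the signal over background limits what can be seen, and BLID in LCC9 and MCF7 lay at background.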

Other observations

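The tests of let-7 targets were chosen only after DICER1 had been seen to be higher. IFNL1, which encodes a secreted interferon, was itself higher in the MCF7 arrays labelled BLID shRNA. It averaged 7.31 ± 0.15 (log2, SD, n = 4) against 4.69 ± 0.45, a difference of at least 2.62, since the controls lay below 5.92. In LCC9 and MDA-MB-231 both groups lay below 5.92, but those of LCC9 were fully apart, higher in the arrays labelled BLID shRNA (exact permutation p = 0.0286, the smallest possible). IFNL1 was named after its values were seen.

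Several genes named for 1 line also changed in another. GJA1, connexin 43, averaged 6.08 ± 0.05 (n = 4) against 7.61 ± 1.01 in MCF7, a fall of 1.53 on the log2 scale. TMEM109, a nuclear and reticulum membrane protein, fell by 0.49 in LCC9 and 0.74 in MCF7 on the log2 scale. S100P rose by 0.87 in MCF7, and CYP1B1, which oxidizes estrogens, rose by 1.03 in LCC9 and 0.59 in MCF7. AOX1, aldehyde oxidase, rose by 0.56 in LCC9, opposite to its fall in MDA-MB-231.

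DICER1, the enzyme that makes mature microRNAs, was higher in the arrays labelled BLID shRNA of all 3 lines and is itself a target of let-7. Weaker repression by let-7 would raise other targets too, and 20 of 26 listed targets were measured. In MDA-MB-231 their median log2 change was 0.24 (quartiles 0.07 to 0.54; 10 higher and 3 lower; camera adjusted p = 0.000152; adjusted p = 0.00243 with an estimated correlation), so weaker let-7 repression may contribute there, although other causes were not tested and THBS1 is also in the mesenchymal list. In LCC9 the median was 0.059 (quartiles -0.13 to 0.22; 4 higher and 2 lower) and in MCF7 0.019 (quartiles -0.17 to 0.20; 5 higher and 3 lower), each with a camera adjusted p of 0.321. With medians near 0 and members that moved both ways, the test leaves the explanation open in those lines. No small RNA was measured.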
